A study of Homo sapiens with 4 samples.

How the data were processed

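Total RNA of the human colon carcinoma line HCT116, grown in McCoy's 5A medium, was sequenced after treatment with PBS, vitamin C, 5-Aza-CdR or the combination of both compounds, with 1 library per group. Per the labels' protocols, RNA was extracted with Trizol, cleaned on columns with a DNase I step, depleted of ribosomal RNA and made into directional libraries. Per the submitters' processing notes, reads were aligned to hg19 with TopHat2 and compared with Cuffdiff, with no versions given. The authors deposited 6 tables, 1 for each pair of the 4 libraries, each with 59337 loci. Per the file headers, each table gives the FPKM of both libraries, that is fragments per unit of transcript length and of mapped fragments. Checked on the values, the FPKM of 1 library in 2 tables differ by a constant factor, so the authors scaled each pair of libraries separately. The log2 fold in the authors' deposited tables is the control library over the treated one in each comparison named here, the opposite sign to the folds printed here. The p-value and q-value in the authors' deposited tables compare the reads of 2 libraries and not the treatments, since there are no replicates.

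Loci without a gene name (31730), loci naming several genes (624) and named loci on alternative or unplaced contigs (1196) were left out of the gene comparisons. Among 23625 symbols on primary chromosomes, 1681 of small RNAs were left out, since their FPKM depends on fragment size, which left 21944. For the 1371 symbols with several loci, the locus with the highest summed FPKM was taken. Values with a status of FAIL or HIDATA in the authors' deposited tables were left out. A gene was kept in a comparison if the larger of its FPKM was at least 1. The fold was the log2 ratio of both FPKM with 0.5 added to each, and genes past 2-fold were counted in each direction. Because the median of genes at 1 FPKM or more in both libraries was not 0, folds of single genes and lists are given relative to that median, and counts are given both as scaled by the authors and centred on it. Single-gene FPKM are printed for all 4 libraries on the scale of the table of 5-Aza-CdR and PBS, reached with a constant factor per library (1.27 and 0.885 for the linking libraries). Locus coordinates are those of the authors' deposited tables on hg19, and a locus can span more than its gene.

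The gene lists (31, of which 1 held structural RNAs left out of the folds), the filters, the size of 2-fold, the alternatives and the rule for named genes were fixed before the data were examined. A list's median was ranked among 10000 random lists of the same size matched on mean expression in 20 bins, and it was said to stand apart below percentile 2.5 or above 97.5. About 5% of lists of unrelated genes do so by chance, and lists with fewer than 5 kept genes were not ranked. The random lists draw genes singly, so a list whose genes vary together between cultures can stand apart without a treatment effect. A named gene is one of the 8 highest or 6 lowest of a main comparison, one of the 3 highest or 3 lowest of a secondary one, one of the 5 most above or 4 most below additivity, one of the 4 members of a list with the largest fold, or one of a fixed set of methylation, interferon, germline and stress genes. IFI44L belonged to that set, but its locus also names IFI44 and was left out. Genes outside this rule are said to be chosen after their values were seen. Additivity means that the effect of vitamin C with 5-Aza-CdR equals its effect alone on the log2 scale. For overlaps of comparisons with the same PBS library, 100 pairs of unchanged libraries were simulated, and taking lists of the same sizes from them was chosen after seeing the data. Effective library size is what the authors' scaling divides by, estimated from the commonest ratio of loci under 0.2 FPKM in both libraries. Symbols were matched to GENCODE 29 for the median length of their annotated transcripts and for small RNAs held within genes, with 19517 (88.9%) found.

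The steps were tested on simulated data made from the vitamin C and PBS comparison with 11872 genes. All 50 genes changed by 3 and all 50 changed by -3 on the log2 scale were found past 2-fold, with 49 of 50 at 1.5 and 50 of 50 at -1.5. None of 11672 unchanged genes passed, under an assumed noise that is small. Of 200 random lists of unchanged genes, 13 (6.5%) stood apart, which does not give the rate for lists whose genes vary together. The alternatives were other pseudocounts (0.1 and 1 FPKM), no floor or a floor of 5 FPKM, sizes of 1.5-fold and 4-fold, other scalings, small RNAs kept, folds chained through another library, loci of status OK only, the authors' calls and unmatched random lists. Leaving out genes that hold a microRNA or snoRNA, and symbols with several loci, was chosen after seeing the data. Read counts are not given in the tables analysed, so no counting interval is given. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 was used.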

Results

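Ribosomal-depleted total RNA was measured in HCT116 colon carcinoma cells treated with PBS, with vitamin C (ascorbate, a cofactor of iron- and 2-oxoglutarate-dependent dioxygenases such as the TET enzymes), with 5-Aza-CdR (decitabine, a nucleoside that traps DNA methyltransferases) or with both. Each of the 4 groups held 1 library, so no difference below has an error between cultures, and doses and times are not given in the labels. The number of named genes at 1 FPKM or more was 11889 in PBS, 11892 with vitamin C, 12368 with 5-Aza-CdR and 12330 with the combination. The number of reads is unknown from the tables, but the commonest ratio among the lowest values put the effective library size at 0.986 times that of PBS with vitamin C, 1.13 with 5-Aza-CdR and 1.39 with the combination. Folds are log2 values relative to the median gene unless a scale is named.

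The comparison of 5-Aza-CdR with PBS asks which transcripts differ after a DNA methylation inhibitor. Germline genes, cancer-testis antigens and interferon-stimulated genes were higher with 5-Aza-CdR, while genes of the integrated stress and unfolded protein response and ribosomal protein genes were lower. MAGEA4, a cancer-testis antigen on chromosome X from 151081361 to 151093642, was at 0.0160 FPKM in PBS and 62.8 with 5-Aza-CdR. UCHL1, a deubiquitinase of neurons on chromosome 4 from 41258898 to 41270446, was listed at 0 in PBS and at 62.2 FPKM with 5-Aza-CdR. GDF15, a stress cytokine on chromosome 19 from 18496968 to 18499986, was 155 FPKM in PBS and 8.08 with 5-Aza-CdR, and its gene holds a small RNA.

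Of 76 cancer-testis antigens in the list, 42 were kept here, against 12 in the comparison of vitamin C with PBS. Of the 42, 32 were at least 2-fold higher and 0 lower, and the list median of 3.19 stood at percentile 100 of random lists. A gene under 1 FPKM in PBS was kept only if it reached 1 FPKM with 5-Aza-CdR, so it could only come out higher. That filter raises the counts and medians of lists mostly silent in PBS, here and with the combination. PAGE5 and CTAG2 were listed at 0 in PBS and at 42.8 and 25.6 FPKM with 5-Aza-CdR, and similar members of their gene families could share reads with them. MAGEC2 went from 0.0423 to 31.4 FPKM. MAGEA3 was already at 18.3 FPKM in PBS and was 27.5 with 5-Aza-CdR. Of 61 germline genes of meiosis and the piRNA pathway, 28 were kept, against 9 in the comparison of vitamin C with PBS. Among the 28, 20 were at least 2-fold higher, with a median of 2.73 at percentile 100. TKTL1 was 0.0830 FPKM in PBS and 43.1 with 5-Aza-CdR, and TDRD12, a piRNA pathway protein, was 0.104 and 13.6. DAZL, an RNA-binding protein of germ cells, was 0.00984 FPKM in PBS and 9.57 with 5-Aza-CdR. Genes reported methylated in colorectal cancer had a median of 0.81 at percentile 100. Of 80 in that list 34 were kept, with 14 at least 2-fold higher and 4 lower. NPTX2 was 0.0256 and 4.66 FPKM, SFRP1, a secreted WNT antagonist, was 0.0204 and 2.74, and CHFR, a mitotic checkpoint ligase, was listed at 0 and at 2.68. Imprinted genes had a median of 0.38 at percentile 99.63, led by PEG10 at 1.24 FPKM in PBS and 13.4 with 5-Aza-CdR.

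Of 49 interferon-stimulated genes kept, 41 were at least 2-fold higher with 5-Aza-CdR and 0 lower, with a median of 1.83 at percentile 100. IFI27 was 10.7 FPKM in PBS and 302 with 5-Aza-CdR, MX1, an antiviral GTPase, was 0.896 and 13.9, and ISG15, a ubiquitin-like modifier, was 276 and 875. Genes of double-stranded RNA and DNA sensing had a median of 0.33 at percentile 99.65, with 4 of 23 at least 2-fold higher. That list, called sensors below, also holds adaptors, kinases and transcription factors, while DDX58 and IFIH1 are in the interferon list. MB21D1, the DNA sensor cGAS, was 0.0708 FPKM in PBS and higher with 5-Aza-CdR by 2.78. Genes of antigen presentation by MHC class I had a median of 0.40 at percentile 99.77, and PSMB8, an immunoproteasome subunit, was 0.101 and 2.32 FPKM. Inflammatory genes of NF-kB had a median of 0.78 at percentile 100, with IL32 at 0.281 and 5.56 FPKM. Type III interferon IFNL1 was 0.0437 FPKM in PBS and higher with 5-Aza-CdR by 2.27, while the list of interferons, receptors and chemokines did not stand apart (median 0.13, percentile 58.0).

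The integrated stress response and unfolded protein list had a median of -0.75 at percentile 0, with 15 of 35 genes at least 2-fold lower and 0 higher. PHGDH, which starts serine synthesis, was 100.4 FPKM in PBS and lay at -2.75 with 5-Aza-CdR, TRIB3 was 132 FPKM in PBS and lay at -2.71, and ASNS, asparagine synthetase, was 218 FPKM in PBS and 31.8 with 5-Aza-CdR. DDIT4, an inhibitor of mTORC1 signalling, was 236 and 24.2 FPKM. Cytosolic ribosomal protein genes, which can share reads with processed pseudogenes, had a median of -0.93 at percentile 0, with 22 of 57 at least 2-fold lower, and RPS6 was 3265 FPKM in PBS and 960.3 with 5-Aza-CdR. Of 57 replication-dependent histone genes, many of near-identical sequence, 32 were at least 2-fold lower and 19 higher, with a median of -1.28 at percentile 0. Of the 19, 13 were under 1 FPKM in PBS and by the filter could only come out higher. Among the 44 histone genes at 1 FPKM or more in PBS, 32 were lower and 6 higher. HIST1H4A was 734 FPKM in PBS and 48.7 with 5-Aza-CdR, and HIST1H4F was listed at 0 and at 22.4. The summed FPKM of the histone list was 19780 in PBS and 4949 with 5-Aza-CdR.

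WNT targets had a median of 0.42 at percentile 99.24, with AXIN2 at 2.15 FPKM in PBS and 8.13 with 5-Aza-CdR. Mesenchymal transition genes had a median of 0.78 at percentile 100, with SPARC at 1.79 and 14.0 FPKM, and cholesterol synthesis genes had 0.38 at percentile 100, with SQLE, squalene epoxidase, at 0.571 and 15.1. Cell cycle genes stood apart with a median of only 0.09 (percentile 99.9), though not among unmatched random lists. DNMT1, the maintenance methyltransferase, was 40.7 FPKM in PBS and 28.0 with 5-Aza-CdR, -0.14 relative to the median gene, and DNMT3B was 4.52 and 10.5, or 1.52. The p53 targets did not stand apart (median -0.05, percentile 33.5), and CDKN1A and MDM2 lay at 0.04 and -0.05.

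Of 12813 genes kept, 791 were at least 2-fold higher and 1287 lower as scaled by the authors, and 1127 and 383 after centring, since the median gene was at -0.39. In the authors' deposited table, 82 of the kept genes were higher and 9 lower at a q-value under 0.05. The q of UCHL1 in the authors' deposited table was 0.00683 and that of PHGDH was 0.0348. With a floor of 5 FPKM, the sensors (0.15), WNT targets (0.18) and genes reported methylated in colorectal cancer (0.21) no longer stood apart. The largest folds include SNAR-H and SNAR-I, short noncoding RNAs listed at 0 in PBS whose FPKM depends on fragment size, and TOMM40L, REXO1 and DGAT1, which stood out in a single library each and hold a small RNA.

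Vitamin C against PBS asks what ascorbate does alone. Interferon-stimulated genes were higher with vitamin C, and few other genes passed 2-fold. Of 43 kept, 22 were at least 2-fold higher and 0 lower relative to the median gene, and the median of 1.06 stood at percentile 100. IFI6 was 67.6 FPKM in PBS and 272 with vitamin C, and IFI27, on chromosome 14 from 94577079 to 94583036, was 10.7 and 43.1. IFITM1, a membrane protein that restricts viral entry, was 45.6 FPKM with vitamin C, higher than in PBS by 1.96. OAS1 and OAS3, which make the activator of RNase L, were 1.08 and 4.13 FPKM, and 6.82 and 22.9.

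The RNA sensors DDX58 (RIG-I) and IFIH1 (MDA5), counted among the interferon-stimulated genes, lay at 1.49 and 1.34 relative to the median gene, and the transcription factor IRF7 at 1.29. MX1 was 0.896 FPKM in PBS and 1.79 with vitamin C. The cancer-testis list did not stand apart (median -0.00, percentile 53.1, 12 genes kept) and neither did the germline list (median 0.11, percentile 87.6, 9 genes kept). UCHL1 was at 0.0264 FPKM with vitamin C and MAGEA4 at 0.0322. Genes of MHC class I presentation (median 0.18, percentile 100) and RNA and DNA sensing (0.09, percentile 99.3) stood apart, with no member at least 2-fold away. So did cell cycle genes (0.12), replication-dependent histones (0.07) and neuronal markers (0.26) on the high side, and ribosomal proteins (-0.23), oxidative phosphorylation (-0.18) and p53 targets (-0.06) on the low side. The p53 targets no longer stood apart without genes that hold a small RNA, and neuronal markers with no floor. Hypoxia targets did not stand apart (median -0.06, percentile 25.2), and TET1, TET2 and TET3 lay at -0.05, 0.02 and 0.28.

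Of 11844 genes kept, 25 were at least 2-fold higher and 10 lower as scaled by the authors, and 28 and 9 after centring. The interferon list held 20 of the 25, and 5 of the 10 lower genes held a small RNA. In the authors' deposited table, 18 kept genes were higher and 0 lower, and IFI27, IFI6, IFIH1, IFIT1, IFITM1, IRF7, ISG15, OAS1, OAS3 and PARP10 had a q of 0.0368. The highest folds of all, UBQLN4 and CEMP1, and the lowest, DGAT1, each stood out in 1 library alone.

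**Figure D1:**
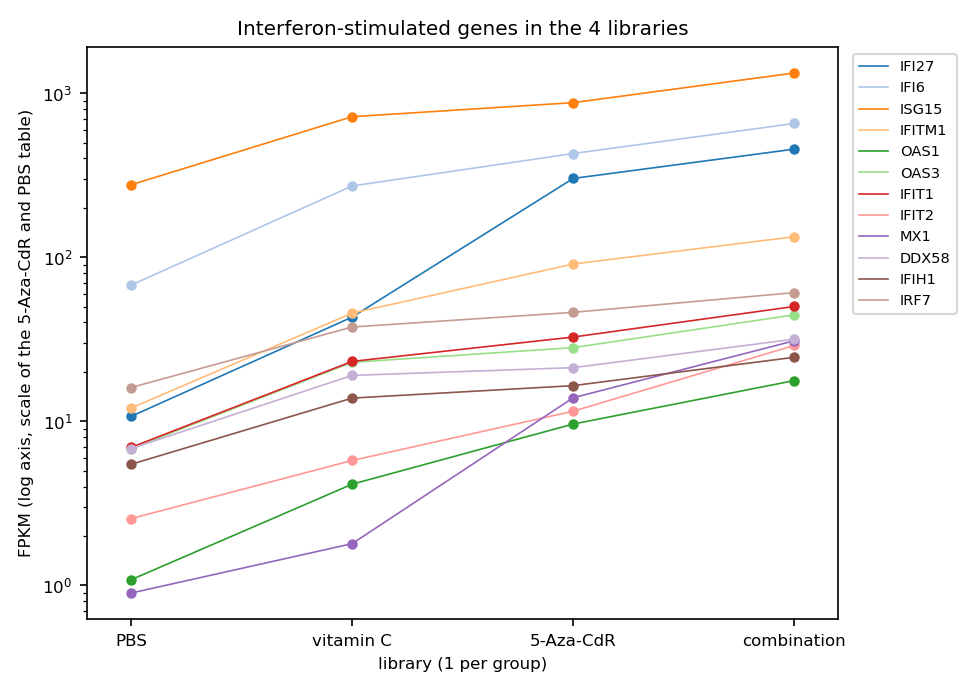
FPKM of 12 interferon-stimulated genes (log axis) in the 4 libraries, 1 point per library, with lines joining the points of a gene. ISG15 goes from 276 FPKM in PBS to 718 with vitamin C, 875 with 5-Aza-CdR and 1326 with the combination.

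The combination against PBS asks what both compounds do together. The same groups led as with 5-Aza-CdR alone, and interferon-stimulated genes were higher still. Of 51 interferon-stimulated genes kept, 49 were at least 2-fold higher, with a median of 2.37 at percentile 100. IFI27 was 10.7 FPKM in PBS and 456 with the combination, MX1 was 0.896 and 30.9, and OAS1 was 1.08 and 17.7. Cancer-testis antigens (median 3.40, 33 at least 2-fold higher of 42 kept from 76) and germline genes (2.71, 23 of 31 kept from 61) stood at percentile 100.

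Of 20 NF-kB and inflammatory genes, 12 were at least 2-fold higher with the combination (median 1.04, percentile 100), with CXCL1 at 0.917 FPKM in PBS and 3.90, and IL32 higher by 4.38. MHC class I genes had a median of 0.72, with 6 of 18 at least 2-fold higher, among them TAP1, the peptide transporter, at 9.54 and 19.1 FPKM. Genes reported methylated in colorectal cancer (0.99, 19 of 38 higher and 5 lower), mesenchymal transition genes (0.97, 12 of 24 higher), imprinted genes (0.40), RNA and DNA sensors (0.41) and cell cycle genes (0.14) also stood apart on the high side. On the low side stood histones (-1.32, 31 of 57 at least 2-fold lower and 20 higher), ribosomal proteins (-1.03, 30 of 57 at least 2-fold lower) and the stress response list (-0.75, 14 of 35). GDF15 was 155 FPKM in PBS and 4.95 with the combination, and PHGDH was 100.4 and 8.98. Cholesterol genes (0.06, percentile 94.2) and WNT targets (0.16, percentile 78.7), which stood apart with 5-Aza-CdR alone, did not here. With a floor of 5 FPKM, sensors (0.15), genes reported methylated in colorectal cancer (0.18) and imprinted genes (0.31) no longer stood apart, nor did cell cycle genes among unmatched random lists.

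Of 12944 genes kept, 890 were at least 2-fold higher and 1912 lower as scaled by the authors, and 1425 and 514 after centring, with the median gene at -0.47. In the authors' deposited table, 81 kept genes were higher and 2 lower. The combination and 5-Aza-CdR alone shared 713 higher genes, of 787 and 755 among 12720 kept in both, and 1219 lower genes, of 1908 and 1285. Independent lists would share 46.7 and 193, and lists of the same sizes from simulated unchanged libraries against the same PBS library shared 204 and 676 on average, so part of the overlap may come from the shared library. Of 24 genes higher with vitamin C, 22 were also higher with the combination, where unchanged libraries shared 7.59 on average and 12 at most, and 22 of 25 were also higher with 5-Aza-CdR (7.87 and 12). The simulation drew noise for each gene singly, while 20 of the 25 belong to the interferon list and may move together. A PBS culture low in these genes could give the overlap too, which the simulation cannot exclude. Of 10 genes lower with vitamin C, 6 were also lower with the combination and 7 with 5-Aza-CdR, within the range of 1 to 10 that unchanged libraries shared.

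**Figure D2:**
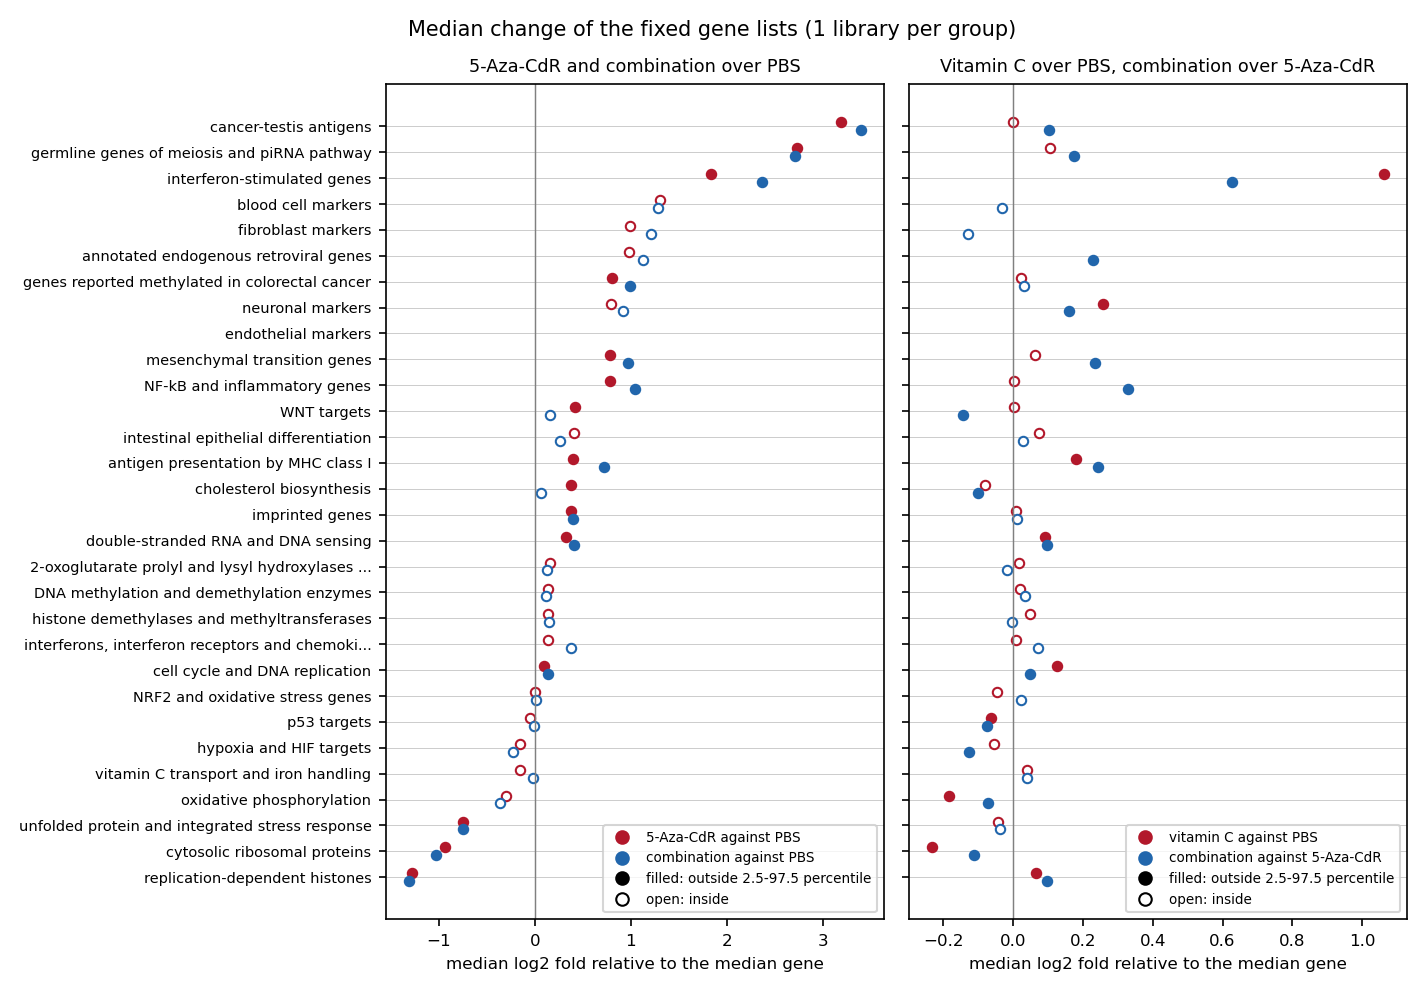
Median log2 fold of each gene list relative to the median gene, with 5-Aza-CdR and the combination over PBS on the left and the effect of vitamin C without and with 5-Aza-CdR on the right, on an axis of its own. Filled points stand apart from random lists, lists with too few genes have no point, and interferon-stimulated genes lie at 1.06 and 0.63 on the right.

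The combination against 5-Aza-CdR asks what vitamin C adds to the methylation inhibitor. Interferon-stimulated genes were again higher, by a median of 0.63 (percentile 100), though 5 of 50 passed 2-fold. IFIT2 was 11.5 FPKM with 5-Aza-CdR and higher by 1.37 with the combination, MX1 was 13.9 and 30.9 FPKM, and RSAD2 (viperin) was 0.791 and 2.62. The type III interferons IFNL1 and IFNL2, the second nearly identical to IFNL3, were higher by 1.41 and 1.35, at 4.40 and 2.25 FPKM with the combination, but their list of 16 did not stand apart (median 0.07, percentile 88.7). NF-kB and inflammatory genes had a median of 0.33 at percentile 100, with the neutrophil chemokines CXCL2 at 1.90 and 4.08 FPKM and CXCL8 at 21.1 and 39.4.

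For 42 interferon-stimulated genes kept in all 4 main comparisons, FPKM were compared without centring. By these, 41 were higher with vitamin C than with PBS and all 42 were higher with the combination than with 5-Aza-CdR. For 33 of them the order was PBS, vitamin C, 5-Aza-CdR, combination. The median gene lay at -0.39 with 5-Aza-CdR and -0.47 with the combination against PBS, so these counts depend on the scaling. Relative to the median gene, all 42 were higher with vitamin C both without and with 5-Aza-CdR. Cancer-testis (0.10) and germline genes (0.18), MHC class I genes (0.24), mesenchymal transition genes (0.23), endogenous retroviral genes (0.23), neuronal markers (0.16), sensors (0.10), histones (0.10) and cell cycle genes (0.05) also stood apart on the high side. WNT targets (-0.14), hypoxia targets (-0.13), ribosomal proteins (-0.11), cholesterol genes (-0.10), p53 targets (-0.07) and oxidative phosphorylation (-0.07) stood apart on the low side, and no member of these lists passed 2-fold. Under at least 1 alternative, retroviral genes (0.21), neuronal markers (0.052), sensors (0.073), cell cycle genes (0.047) and p53 targets (-0.030, with no floor) no longer stood apart. KRT17, a keratin, was 3.35 FPKM with 5-Aza-CdR and 8.38 with the combination.

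Of 13196 genes kept, 15 were at least 2-fold higher and 11 lower as scaled by the authors, and 19 and 9 after centring. Of the lower ones 7 held a small RNA, and TOMM40L, REXO1 and NOP56 stood out in the 5-Aza-CdR library alone. In the authors' deposited table IFIT2, MX1, RSAD2 and KRT17 were higher with a q of 0.0476.

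Whether vitamin C acts alike without and with 5-Aza-CdR is the question of additivity. Interferon-stimulated genes lay below it, with a median departure of -0.35 at percentile 0, and 6 of 50 were at least 2-fold below and 1 above. On the linear scale without centring, 25 of the 42 gained more FPKM from vitamin C with 5-Aza-CdR than without, and the others did not. On that scale the median gene was 0.765 times PBS with 5-Aza-CdR and 0.721 times with the combination. The count therefore depends on the scaling and was not repeated after centring. NF-kB and inflammatory genes (0.27, percentile 100), mesenchymal transition genes (0.22, percentile 100) and interferons with their receptors and chemokines (0.16, percentile 99.6) lay above additivity, as did oxidative phosphorylation (0.14, percentile 99.5). Below it also lay fibroblast markers (-0.35), intestinal differentiation genes (-0.11), hypoxia targets (-0.08), cholesterol genes (-0.06), cell cycle genes (-0.04) and histones (-0.02), with no member at least 2-fold away. In all, 4 lists stood above, 7 below and 18 not apart. Of 13259 genes kept, 27 were at least 2-fold above and 22 below. The furthest above were DGAT1, DEFB109P1, ANKRD54, CPSF1 and SNAR-D, and the furthest below TOMM40L, REXO1, NOP56 and UBQLN4. DGAT1, CPSF1, TOMM40L, REXO1, NOP56 and UBQLN4 stood out in a single library each, and ANKRD54 holds a small RNA.

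Against vitamin C instead of PBS, 5-Aza-CdR and the combination gave the same leading groups. With 5-Aza-CdR, interferon-stimulated genes had a median of 0.76 and 18 of 49 were at least 2-fold higher, and with the combination 1.28 and 36 of 51. Cancer-testis antigens had medians of 3.06 and 3.39, ribosomal proteins -0.68 and -0.81, and the stress response list -0.83 and -0.76. As scaled by the authors, 818 genes were at least 2-fold higher and 781 lower with 5-Aza-CdR, and 924 and 1224 with the combination. In the authors' deposited tables, 87 kept genes were higher and 17 lower with 5-Aza-CdR, and 86 and 4 with the combination.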

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

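All tests below on loci without a gene name and on interferon-stimulated genes, and for ribosomal protein genes the test of scaling and the test on genes outside the list, were chosen only after the result was seen. Loci without a gene name were left out of the comparisons above, yet many were called in the authors' deposited tables. In the authors' deposited tables, 253 such loci were higher with 5-Aza-CdR than with PBS, 294 with the combination than with PBS, 6 with vitamin C than with PBS and 22 with the combination than with 5-Aza-CdR. Lower in the authors' deposited tables were 0, 0, 4 and 6 such loci, in the same order. The effect of vitamin C on ANKRD54 went in opposite directions, -2.15 alone and 1.73 with 5-Aza-CdR, a difference that was not tested, in a gene that holds a microRNA.

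Loci over 100 kb from any named locus (8379) had a median of 0 FPKM in PBS and 0.186 with 5-Aza-CdR, and 44.7% and 95.2% were above 0. A wrong scaling factor would move named genes alike, but these loci lay 1.88 higher on the log2 scale than the median named gene, and deeper sequencing alone would give no larger step from PBS to 5-Aza-CdR, whose effective library sizes differ by 1.13 times, than from 5-Aza-CdR to the combination (1.21 times), yet the first was larger by 1.12. Genomic DNA could add reads all over the genome, and it stays open: a first test gave its side, as only 0.398% of called loci exceeded the 99th percentile of olfactory receptor genes, genes silent in most cells, with 5-Aza-CdR (4.41 FPKM), but it was set aside after its value was seen because that percentile was already 2.41 FPKM in PBS and called loci had a median of 0.375 FPKM with 5-Aza-CdR. The mean gain of olfactory receptor genes was 35.9% of that at uncalled far loci, and the median gain of called loci was 7.91 times the olfactory mean, a replacement test chosen after the first, and both lie between what genomic DNA and its absence would give. Transcription started by loss of DNA methylation, the biological explanation that the 5-Aza-CdR group gives, cannot be told apart from it here, since no library without reverse transcription was analysed here, nor from assembly of these loci out of reads of the 5-Aza-CdR or combination library, which would also leave many (55.3%) at 0 in PBS.

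Interferon-stimulated genes were higher with vitamin C than with PBS by a median of 1.06. RNA of the 5-Aza-CdR library mixed into the vitamin C library would bring cancer-testis and germline transcripts in equal share, but 27 such genes had a median of 0.00830% of their 5-Aza-CdR rise, against 62.6% for 34 interferon-stimulated genes. Noise of genes with few reads is argued against by the 26 members at 10 FPKM or more, whose median of 1.05 stood at percentile 100. Another difference between the cultures than vitamin C may be the source and cannot be told apart from it, with 1 library per group.

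Ribosomal protein genes were lower with 5-Aza-CdR, and a wrong scaling factor would leave them at the median gene, from which they lay at -0.93. A bias by annotated transcript length among the kept genes is argued against by random lists matched on expression and that length, among which the median stood at percentile 0. The length was the median over all annotated transcripts of a symbol, not that of the transcripts expressed. A bias by expressed length therefore stays open. The small RNAs RNU11, RNU12, RNU4ATAC and RNU6ATAC were left out of that test and were lower too. RNU12 was 2706 FPKM in PBS and 960 with 5-Aza-CdR, and RNU6ATAC was 9553 and 2493. It was not tested whether their fall has the same cause as that of the ribosomal protein genes. A fall of all abundant genes could bring them down: the first test of it, written before its result was seen, put the list at percentile 2.96 among random lists in 100 expression bins, on the side of that explanation, and it was set aside after its value was seen because 38.6% of the drawn genes were members of the list. With members left out of the draws, a replacement test chosen after the first, the list stood at percentile 0.06, and other genes among the most abundant had a median of -0.24. An effect of 5-Aza-CdR on ribosomal protein transcripts is thus a hypothesis that rests on that replacement and on 1 library per group.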

How the results depend on the processing

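No paired analysis was possible because each group has 1 library and no replicate numbers, and no library could be left out for the same reason. No list that stood apart and no named gene past 2-fold reversed its direction under any alternative, but the balance of genes higher and lower with 5-Aza-CdR did with the scaling. Of 202 counts recomputed, 120 stayed within 1.5 times the value reported and 82 did not. Of 1343 list medians, 1293 kept their side of the percentile limits, 18 no longer stood apart and 32 newly did. Of 8840 folds of named genes 8776 kept their side of 2-fold, 23 fell short of it and 41 newly passed it. The 839 folds under centring could not change, and leaving out or keeping other genes moves a fold only through the median gene. Leaving out genes that hold a microRNA or snoRNA, and leaving out symbols with several loci, were chosen after seeing the data. The number of reads is unknown, so what low FPKM can show is limited by the floor of 1 FPKM alone.

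With each library rescaled to the same sum, on which RMRP (137529 FPKM in PBS) and RPPH1 (83906) weigh, genes higher were 2911 with 5-Aza-CdR, 3698 with the combination and 55 with vitamin C against PBS, 50 with the combination against 5-Aza-CdR, and 2586 with the combination and 2032 with 5-Aza-CdR against vitamin C. Genes lower were 144 with 5-Aza-CdR and 189 with the combination against PBS, and 251 with the combination and 210 with 5-Aza-CdR against vitamin C, with 52 above and 61 below additivity. Centred on the median gene, 1425 were higher and 514 lower with the combination against PBS, 383 lower with 5-Aza-CdR against PBS, and 434 with the combination and 327 with 5-Aza-CdR lower against vitamin C. So whether more genes were lower or higher with 5-Aza-CdR depends on the scaling.

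With a floor of 5 FPKM, which tests fewer genes, 221 genes were higher with 5-Aza-CdR and 260 with the combination against PBS, 264 with the combination and 221 with 5-Aza-CdR against vitamin C, 9 with the combination against 5-Aza-CdR, 6 were lower with vitamin C and 11 lay above additivity. With a pseudocount of 0.1 FPKM, 34 were higher and 20 lower with the combination against 5-Aza-CdR, 19 lower with vitamin C, and 72 above and 61 below additivity. A pseudocount of 1 FPKM left 14 above additivity, and loci of status OK only left 17.

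At a size of 1.5-fold, genes higher were 59 with vitamin C against PBS, 114 with the combination against 5-Aza-CdR and 1271 with 5-Aza-CdR against vitamin C. Genes lower were 4033 with 5-Aza-CdR, 5047 with the combination and 45 with vitamin C against PBS, 99 with the combination against 5-Aza-CdR, and 3710 with the combination and 2833 with 5-Aza-CdR against vitamin C, with 137 above and 115 below additivity. At 4-fold, genes higher were 327 with 5-Aza-CdR, 390 with the combination and 3 with vitamin C against PBS, 2 with the combination against 5-Aza-CdR, and 380 with the combination and 323 with 5-Aza-CdR against vitamin C. Genes lower were 60, 113 and 4 against PBS in the same order, and 68 with the combination and 47 with 5-Aza-CdR against vitamin C, with 6 above and 11 below additivity. Shared at 4-fold were 308 higher and 55 lower genes for 5-Aza-CdR and the combination, 1 higher and 2 lower for vitamin C and the combination, and 1 higher and 3 lower for vitamin C and 5-Aza-CdR. Lists of these sizes from simulated unchanged libraries shared 80.7, 38.1, 1.49, 1.80, 1.49 and 1.78 in the same order, so at 4-fold the overlaps of vitamin C are no clear excess.

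With small RNA genes kept, 67 genes were higher and 60 lower with vitamin C against PBS, 81 higher and 74 lower with the combination against 5-Aza-CdR, and 65 above and 57 below additivity. Without genes that hold a microRNA or snoRNA, 5 were lower with vitamin C and 4 with the combination against 5-Aza-CdR. Without symbols with several loci these were 6 and 7. By the q-value under 0.05 in the authors' deposited tables, genes higher were 82 with 5-Aza-CdR and 81 with the combination against PBS, 5 with the combination against 5-Aza-CdR, and 86 with the combination and 87 with 5-Aza-CdR against vitamin C. In the authors' deposited tables genes lower were 9, 2 and 0 with 5-Aza-CdR, the combination and vitamin C against PBS, 4 with the combination against 5-Aza-CdR, and 4 with the combination and 17 with 5-Aza-CdR against vitamin C. Where the construction of an alternative does not show it, the cause was not tested.

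Lists that no longer stood apart were these, with their median under the alternative. With a floor of 5 FPKM these were sensors (0.15 with 5-Aza-CdR and 0.15 with the combination against PBS), genes reported methylated in colorectal cancer (0.21 and 0.18), WNT targets with 5-Aza-CdR (0.18) and imprinted genes with the combination (0.31). With no floor they were WNT targets with 5-Aza-CdR (0.44), neuronal markers with vitamin C (0.13) and p53 targets with the combination against 5-Aza-CdR (-0.030). With each library rescaled it was neuronal markers with the combination against 5-Aza-CdR (0.052). Without genes that hold a small RNA they were p53 targets with vitamin C (-0.049) and sensors with the combination against 5-Aza-CdR (0.073). Without symbols with several loci they were WNT targets with 5-Aza-CdR (0.34), p53 targets with vitamin C (-0.055) and retroviral genes with the combination against 5-Aza-CdR (0.21). Among unmatched random lists they were cell cycle genes with 5-Aza-CdR (0.092) and the combination (0.14) against PBS and the combination against 5-Aza-CdR (0.047).

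Lists that newly stood apart with a floor of 5 FPKM were intestinal differentiation with 5-Aza-CdR (0.42). With no floor these were NRF2 genes with 5-Aza-CdR (0.20), with the combination against PBS (0.18) and against 5-Aza-CdR (0.054), and blood cell markers with 5-Aza-CdR (0.90) and the combination (0.96) against PBS. With each library rescaled they were blood cell markers with 5-Aza-CdR (1.2), fibroblast markers with the combination against PBS (1.22) and genes reported methylated with the combination against 5-Aza-CdR (0.10). Fibroblast markers with the combination against PBS did so too with folds chained through another library (1.22), centred folds (1.21), a pseudocount of 1 FPKM (1.09), status OK only (1.21) and without symbols with several loci (1.21), and retroviral genes with 5-Aza-CdR with centred folds (0.98), a pseudocount of 0.1 FPKM (1.09) and status OK only (0.98). Centring moves no relative fold, so with centred folds the draw of random lists alone shifts the call, and for the other alternatives the cause was not tested. Among unmatched random lists, these stood apart against PBS with 5-Aza-CdR and with the combination: retroviral genes (0.98 and 1.12), blood cell markers (1.30 and 1.28), fibroblast markers (0.99 and 1.21), neuronal markers (0.79 and 0.92), hypoxia targets (-0.15 and -0.22) and oxidative phosphorylation (-0.30 and -0.36), with intestinal differentiation for 5-Aza-CdR (0.40), and with vitamin C hypoxia targets (-0.056) and cholesterol genes (-0.080).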

Other observations

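Both hypotheses below, and the values set against them, were chosen only after the results that led to them were seen. TXNIP, a brake on thioredoxin and glucose uptake, was 0.0558 FPKM in PBS, 0.160 with vitamin C, 14.9 with 5-Aza-CdR and 12.4 with the combination, at a locus that spans more than the gene. CBR1, a carbonyl reductase, was listed at 0 in PBS and at 8.45 FPKM with 5-Aza-CdR, while SLC7A11, the cystine transporter, was 22.1 and 2.91. The list of NRF2 and oxidative stress genes holding all 3 did not stand apart with 5-Aza-CdR (median 0.01, percentile 89.8), with 10 of 50 at least 2-fold higher and 3 lower. FTL, the ferritin light chain, was 468 FPKM in PBS and 880.1 with 5-Aza-CdR, and TFRC, the transferrin receptor, was 91.8 and 77.5, in a list of vitamin C transport and iron handling with a median of -0.15 at percentile 19.04. Hypoxia targets had a median of -0.15 at percentile 17.7 with 5-Aza-CdR, with VEGFA at 46.1 FPKM in PBS and 13.7, and oxidative phosphorylation genes -0.30 at percentile 17.2.

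Enzymes of DNA methylation and demethylation (median 0.14, percentile 94.9), histone demethylases and methyltransferases (0.13, percentile 91.5) and prolyl and lysyl hydroxylases with collagens (0.16, percentile 93.7) did not stand apart with 5-Aza-CdR. Intestinal differentiation genes had a median of 0.40 at percentile 84.6, with KRT20, a keratin of mature colon cells, at 0.175 FPKM in PBS and 5.13 with 5-Aza-CdR. Markers of cell types that a pure line should lack were also read. Kept were 9 of 26 blood cell, 12 of 28 neuronal and 5 of 16 fibroblast markers, against 2, 7 and 3 in the comparison of vitamin C with PBS. Markers under 1 FPKM in PBS were kept only if they reached 1 FPKM with 5-Aza-CdR, so they could only come out higher. Of the markers kept, 5, 5 and 2 were at least 2-fold higher with 5-Aza-CdR, and none of the 3 lists stood apart (percentiles 91.2, 95.4 and 92.4). CD3D, a T cell receptor subunit, was 0.0199 FPKM in PBS and 4.63 with 5-Aza-CdR, and 3 endothelial markers were too few to rank. Annotated endogenous retroviral genes had a median of 0.98 at percentile 97.47 over 5 genes, inside the limit, with 2 at least 2-fold higher and 0 lower. That list holds PEG10, also counted among the imprinted genes, at 1.24 FPKM in PBS and 13.4 with 5-Aza-CdR. ERVMER34-1 was 6.44 FPKM in PBS and 4.41 with 5-Aza-CdR, so the median does not show a rise of retroviral loci as a group. Among structural RNAs, left out of the folds, MALAT1 was 777 FPKM in PBS and 541 with 5-Aza-CdR, and RMRP 137529 and 72273.

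Genes that stood out at least 8-fold in 1 library, with the other 3 within 2-fold of each other, numbered 7, and 5 of them (71.4%) hold a microRNA or snoRNA, against 872 of 13029 genes (6.69%). They are DGAT1 in PBS, CEMP1 and UBQLN4 with vitamin C, NOP56, REXO1 and TOMM40L with 5-Aza-CdR and CPSF1 with the combination.

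Genes on the X chromosome may switch on more often than others when 5-Aza-CdR is given. Of 6361 named genes under 0.1 FPKM in PBS, 297 were at 1 FPKM or more with 5-Aza-CdR, and 49 of these (16.5%) lie on the X chromosome, against 5.79% of all 6361. Without the cancer-testis list, itself rich in X-linked genes, the share was 10.9% (30 of 276), against 5.34% of 6326 genes under 0.1 FPKM in PBS without that list, and with vitamin C 0 genes switched on.

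A second hypothesis was that vitamin C acts on interferon-stimulated genes with the same fold with and without 5-Aza-CdR. The list's median departure from additivity was -0.35 at percentile 0, so the folds were unequal in these 4 libraries. Random lists draw genes singly, so 1 culture high or low in these genes as a group could give that departure too. With 1 library per group the hypothesis cannot be decided.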
